A study of Homo sapiens with 9 samples.

How the data were processed

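RNA from HT1080 cells, a human fibrosarcoma line, was hybridised to 9 one-colour Affymetrix arrays of 54675 probe sets, 3 per group. Per the labels' protocols, collagen at 1.7 mg/ml was left to polymerize for 4 h, cells were seeded on it in medium with 10% serum and left to adhere for 24 h, and treatments were then added. The inhibitor mix held E64 at 250 µM, GM6001 at 100 µM, pepstatin A at 50 µM, and leupeptin and aprotinin at 2 µM each. Labelled cRNA was prepared from 6 µg of total RNA per sample, per the labels. Groups and replicate numbers came from the sample titles, and the series' design text calls the replicates biological. That text names the mix as kinase inhibitors, whereas the treatment protocol and the series title name protease inhibitors, and the protocol's list of compounds was followed here. The titles name a vehicle for the untreated arrays. What the vehicle was, and at which time those cells were harvested, is not given in the sources used here.

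The deposited values are intensities on a linear scale, 1 per probe set and array. The authors' submitted processing notes name R 2.9.2 and RMA without a role. The values themselves were not on a log scale and reached 0, and their quartiles differed between arrays. The mean after trimming 2% at each end was 100 on every array, so each array had been scaled to a common mean by the time of deposit. A common mean removes any change in the total amount of messenger RNA. The summarisation software and the detection calls are not given in the sources used here, so values near or below the pseudocount have no call to separate them from background. The number of arrays limits the precision.

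The design had been written for log2 values. Because the values proved linear, they were transformed as log2(intensity + 16). The pseudocount of 16 was chosen after the scale was seen and before any test was run, and 1 and 64 were added as alternatives after seeing the data. Fold changes are on this scale, which understates the change of dim genes. Probe sets were named through the supplied platform annotation: after 62 control probe sets were left out, 41091 named 1 gene, 1801 named several and 11721 were not listed there, 54613 in all. Of the Entrez identifiers of the first class, 41037 matched the RefSeq gene table and 54 did not, which kept the platform's symbol. Each gene was represented by the probe set with the highest mean over the 9 arrays, giving 19775 genes, and no filter was applied. The mean of 40.6% of the genes lay below the pseudocount. Probe sets cannot separate close paralogs such as metallothioneins, histones and ribosomal proteins with certainty, and these are reported as uncertain. The strand and target of probe sets named for antisense or divergent transcripts were not checked here. No coordinates are given, because the array names no genome build.

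A linear model with 1 mean per group was fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Each of the 3 comparisons was adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Every adjusted p for a single gene comes from this model, and all tests were two-sided. In all, 37 gene lists of 1084 genes were fixed before the data were examined. They covered proteases and matrix, adhesion and cytoskeleton, signalling targets, stress responses, lipid synthesis, organelles, cell cycle, ribosomes and markers of 4 other cell types. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 37 lists within a comparison, and again with the correlation estimated for each list and with fry. The result of 1 list is not reported here, though it is counted among the lists. Genes were named by a rule fixed before the data were examined. It took the 8 largest rises and falls past the threshold with no overlap between the arrays of the groups (5 for 24 h against 4 h). It also took, for each shifted list, the 3 members with the smallest p in its direction, and MMP1, MMP2, MMP14, CTSB, CTSD, CTSL and PLAU whatever their test. Genes named outside the rule are said to be so. Array-level measures were compared with exact permutation tests, where 3 against 3 arrays cannot give a p under 0.1.

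The tests were tested on simulated data first. With 200 of the genes changed in a simulated comparison of 24 h with untreated, 6% of genes changed by 0.5 on the log2 scale, 67.2% of those changed by 1 and 97% of those changed by 2 were recovered, with 11 false calls among 19575 unchanged genes. For 24 h against 4 h the shares recovered were 9%, 70.1% and 98.5% (6, 47 and 65 genes), beside 10 false calls. The changed genes were drawn only from those above the 40th percentile of mean value. The shares therefore do not cover dimmer genes, which were tested in the real data, and were not split by brightness among the rest. A list shifted by 0.5 was called and 0 of 36 other lists were. The noise of each gene was drawn independently in these simulations. They cannot show how often lists of genes that vary together are called falsely, and the correlation estimated for ribosomal proteins was 0.847.

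The alternatives fixed beforehand were the mean of all probe sets of a gene, each probe set on its own, filters at the 40th and 60th percentile of mean value, quantile normalization, median centring, eBayes with a trend and robust settings, a model of the compared groups alone, a minimum log2 change of 1, the replicate number as a block, an estimated correlation for lists, and leaving out each array in turn.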

Results

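Gene expression was measured in HT1080 fibrosarcoma cells, an established human line, growing on top of a thick fibrillar collagen gel. Cells were left untreated or received a mix of protease inhibitors for 4 h or 24 h, with 3 arrays in each group. The mix combined GM6001, an inhibitor of matrix metalloproteinases, with pepstatin A, E64, aprotinin and leupeptin, which inhibit aspartic, cysteine and serine proteases. The comparisons asked how transcript levels had changed after 4 h and after 24 h of inhibition, and how the later profile differed from the earlier one. Values are deposited linear intensities scaled to a trimmed mean of 100 on each array, and are given as mean ± SD (n = 3). The median intensity per array ranged from 14.2 to 18.2.

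The arrays differed in ways that followed the treatment. The poly-A spike transcripts, bacterial RNAs that are added during sample preparation, had a mean log2 intensity of 9.41 ± 0.08 on untreated arrays, 10.29 ± 0.21 at 4 h and 10.72 ± 0.04 at 24 h. They were thus 1.85-fold and 2.49-fold brighter after treatment, each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give. The hybridization controls, which are added later, were 1.09-fold and 1.11-fold brighter (exact p = 0.3 and 0.2). The ratio of 5' to 3' signal of ACTB, a sign of RNA quality, was 0.893 ± 0.034 untreated, 0.723 ± 0.132 at 4 h and 0.697 ± 0.038 at 24 h (exact p = 0.2 and 0.1 against untreated). On the first principal component, which held 21% of the variance, untreated arrays lay between -23.3 and -18.2 and 24 h arrays between 15.6 and 19.7. Replicates 1 and 3 of the 4 h group lay at 8.63 and 15.5, whereas replicate 2 lay at -13.4 and had an ACTB ratio of 0.871 against 0.682 and 0.615.

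**Figure D1:**
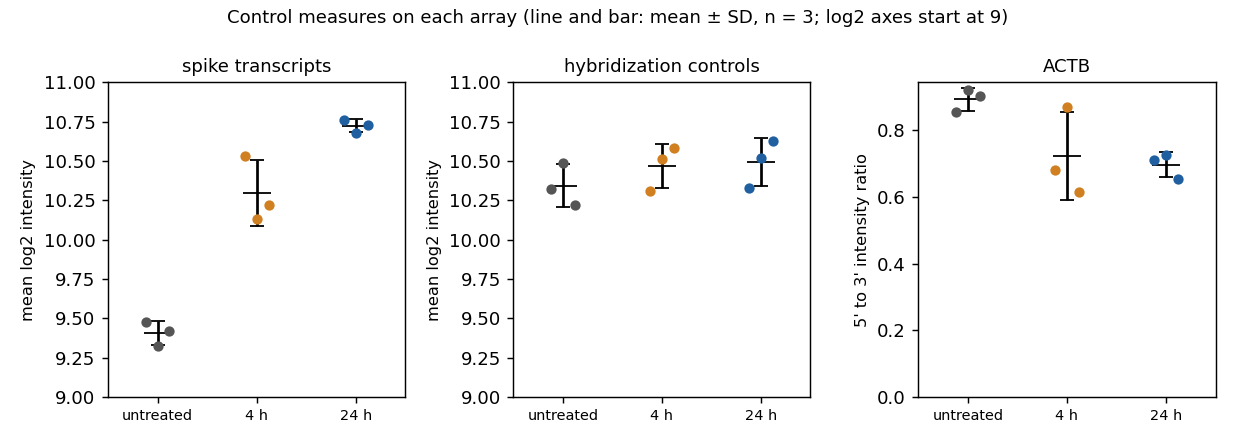
Mean log2 intensity of the spike transcripts and of the hybridization controls, and the 5' to 3' intensity ratio of ACTB, on each array by group, with mean ± SD (n = 3); the log2 axes start at 9. The spike transcripts stood at 9.41, 10.29 and 10.72 in untreated, 4 h and 24 h arrays, while the hybridization controls changed by 1.11-fold or less.

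After 4 h, the chemokine CXCL8 had the largest rise, from 126 ± 23 untreated to 657 ± 42 (4.77-fold, log2 change 2.25 ± 0.15 SE, adjusted p = 0.00105). Other genes of NF-kB signalling rose with it: NFKBIA, which encodes an inhibitor of NF-kB, from 571 ± 46 to 1375 ± 132 (adjusted p = 0.00776), and TNFAIP3, a negative regulator of the pathway, from 93.2 ± 9.7 to 229 ± 7 (adjusted p = 0.00938). The transcription factor genes EGR1 (47.0 ± 8.4 to 177 ± 11, adjusted p = 0.004) and MAFF (414 ± 12 to 1316 ± 252, adjusted p = 0.00561) rose 3.08-fold and 3.06-fold. CCN2, which encodes connective tissue growth factor, rose from 383 ± 42 to 1140 ± 253 (adjusted p = 0.0212). Altogether 46 genes were higher and 3 were lower than in untreated cells, and 20 of the rises were at least 2-fold.

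Treated and untreated arrays did not overlap in any of these 49 genes, which held for 17.5% of all genes and would hold for 10% by chance. Among called genes such separation nearly follows from passing the threshold, so it adds no support to the calls. MED26, a Mediator subunit (2.53-fold, adjusted p = 0.0442), and NLRP3, an inflammasome sensor (2.35-fold, adjusted p = 0.0365), were also among the largest rises. CNIH2 rose from 5.30 ± 2.17 to 32.9 ± 3.2, near background. The 3 falls were FUT8-AS1 (96.6 ± 12.8 to 42 ± 6.2, adjusted p = 0.0365), RUNX2, an osteoblast transcription factor (229 ± 8 to 117 ± 10, adjusted p = 0.0307), and TMCC3 (87.9 ± 11.9 to 40.4 ± 3.1, adjusted p = 0.0459). For RUNX2, 5 of its 6 probe sets had the opposite sign, and the mean over its probe sets gave a log2 change of 0.04. MED26 and NLRP3 (1 of 3 probe sets each) and FUT8-AS1 (1 of 2) also had a probe set of the opposite sign, and with the mean over probe sets these calls and that of TMCC3 were lost (adjusted p = 0.293, 0.127, 0.446 and 0.0965).

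Of the 37 fixed gene lists, 4 shifted up at 4 h at the preset correlation. The list of inflammatory cytokines and NF-kB targets shifted up (adjusted p = 0.000277, and adjusted p = 0.182 with an estimated correlation). Of its 30 measured genes 3 rose, none fell and 27 did not pass, and 9 were higher and 1 lower when adjusted over the list alone. YAP/TEAD targets shifted up (adjusted p = 0.0108, and adjusted p = 0.445 with an estimated correlation): CCN2 and DLC1 (339 ± 31 to 692 ± 65, adjusted p = 0.0442) rose and 24 of 26 did not pass, with 7 higher and 2 lower when adjusted over the list alone. For DLC1, 2 of its 5 probe sets had the opposite sign, and with the mean over probe sets its call (adjusted p = 0.43) and that of the YAP/TEAD list were lost.

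The list of ATF4 targets and the amino acid response shifted up as well (adjusted p = 0.00197, and adjusted p = 0.182 with an estimated correlation), although none of its 44 genes passed over all genes and 6 were higher when adjusted over the list alone. Its leading members were SESN2 (229 ± 28 untreated and 379 ± 51 at 4 h, adjusted p = 0.0998), EPRS1 (789 ± 123 and 1382 ± 193, adjusted p = 0.102) and CHAC1 (25.3 ± 13.5 and 69.4 ± 7.4, adjusted p = 0.118). Ribosomal protein genes shifted up by a mean of 0.14 on the log2 scale (adjusted p = 0.0162, and adjusted p = 0.813 with an estimated correlation), with none of 36 past the threshold over all genes or adjusted over the list alone. Without replicate 3 of the 4 h group their mean stayed above 0, at 0.0355, but no longer stood above that of the other genes, and the call was lost under quantile normalization and median centring.

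The count at 4 h depended on the arrays and on the model. It fell to between 3 and 14 higher genes when any 1 of the 9 arrays was left out, and to 2 when the 24 h arrays were kept out of the model, whereas a filter at the 40th percentile gave 142 higher and 35 lower. CXCL8, EGR1 and MAFF kept their calls without any single array, with limma adjusted p up to 0.0498 for MAFF. The call of MAFF was lost when the 24 h arrays were kept out of the model (adjusted p = 0.074).

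**Figure D2:**
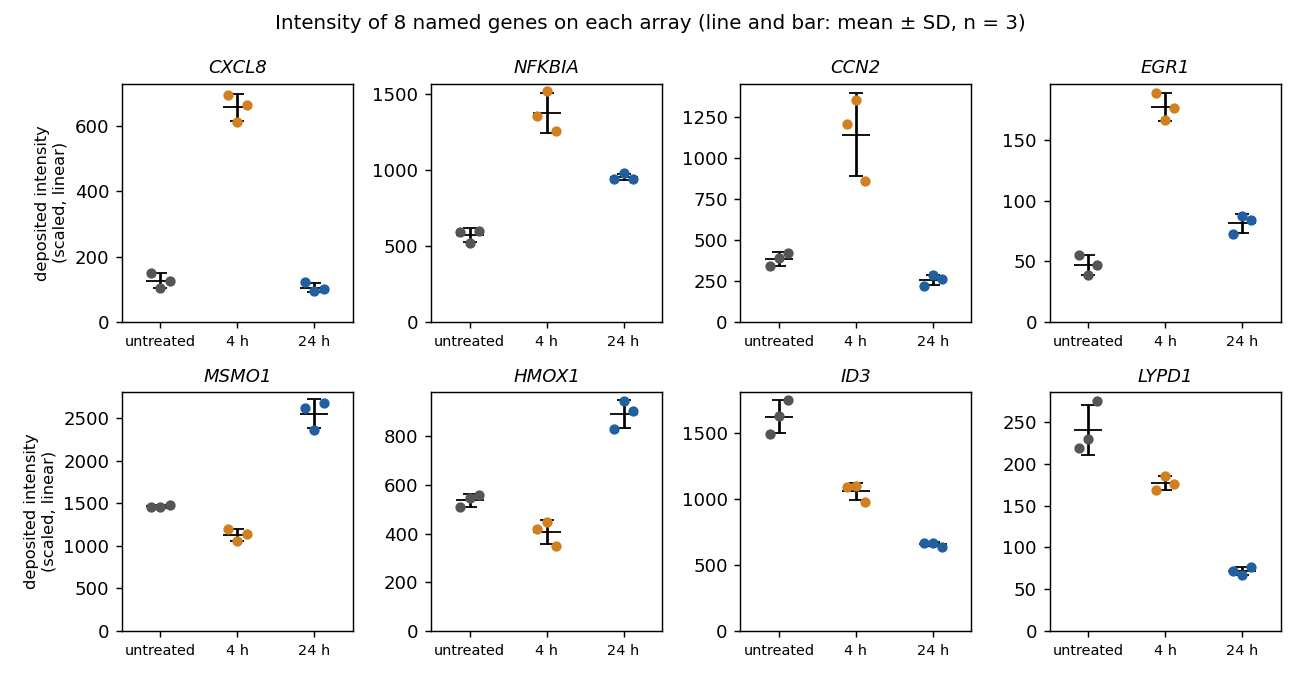
Deposited intensity of 8 named genes on each array, on linear axes from 0, with mean ± SD (n = 3) for untreated, 4 h and 24 h arrays. CXCL8 and CCN2 were highest at 4 h (657 and 1140), MSMO1 and HMOX1 at 24 h (2551 and 893), and ID3 and LYPD1 were lowest at 24 h (657 and 71.8).

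After 24 h, 43 genes were higher and 49 were lower than in untreated cells, 9 and 15 of them by at least 2-fold. Genes of cholesterol synthesis rose: INSIG1, a sterol-responsive regulator of that pathway, from 367 ± 12 to 725 ± 23 (adjusted p = 0.0266), MSMO1 from 1463 ± 15 to 2551 ± 167 (adjusted p = 0.0299) and SQLE, squalene epoxidase, from 435 ± 34 to 730 ± 19 (adjusted p = 0.0485). ID3 and ID1, transcriptional regulators downstream of TGF-beta family signals, fell from 1626 ± 127 to 657 ± 15 (adjusted p = 0.00713) and from 1477 ± 94 to 735 ± 32 (adjusted p = 0.0229). SNAI2, a mesenchymal transcription factor, fell from 766 ± 47 to 366 ± 17 (adjusted p = 0.0229), and LOX, which crosslinks collagen, fell from 393 ± 20 to 213 ± 24 (adjusted p = 0.0485). Treated and untreated arrays did not overlap in any of the 92 genes, which again nearly follows from passing the threshold. It held for 25% of all genes and would hold for 10% by chance.

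The largest rise was SIGLEC15, a sialic acid binding receptor, from 348 ± 70 to 973 ± 159 (2.73-fold, adjusted p = 0.0397). GULP1, an engulfment adaptor, rose 2.43-fold (adjusted p = 0.0166), PAG1 2.31-fold (adjusted p = 0.0322) and SLC31A2, a copper transporter, 2.22-fold (adjusted p = 0.0166), followed by WDPCP, EPC1, TMEM87B and LPIN1 at 2.14-fold to 2.02-fold. The largest fall was LYPD1, from 242 ± 30 to 71.8 ± 4.6 (log2 change -1.55 ± 0.12 SE, adjusted p = 0.00517). SLC26A4, an anion transporter, fell from 77.5 ± 22.8 to 18.5 ± 3.9 (adjusted p = 0.0298), and ADGRG1, an adhesion receptor, from 272 ± 54 to 96.0 ± 17.2 (adjusted p = 0.0427). RGS4, MELTF, ALDH1A3 and PEBP1 fell to 213 ± 18, 354 ± 16, 102 ± 7 and 612 ± 42 from 525 ± 15, 849 ± 41, 254 ± 17 and 1406 ± 39. Probe sets of the opposite sign were found for GULP1 (2 of 5), PAG1 (1 of 3), EPC1 (2 of 4), LPIN1 (1 of 3) and MELTF (2 of 4), and with the mean over probe sets their calls were lost (adjusted p = 0.237, 0.192, 0.274, 0.0971 and 0.198). The calls of WDPCP, ADGRG1, ALDH1A3, PEBP1, SQLE and LOX, whose probe sets had the same sign, were lost there too (adjusted p between 0.0531 for LOX and 0.0968 for ADGRG1).

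At the preset correlation 10 lists shifted up and 8 shifted down at 24 h. None of the 18 calls held with an estimated correlation, where the lowest adjusted p was 0.0743. The estimate was below the preset 0.01 for fatty acid synthesis (-0.0392), mesenchymal genes (-0.0284), NRF2 targets (-0.0215), autophagy (-0.00456) and plasminogen and serine proteases (0.009). For these a higher correlation was not why the call was lost. For the rest of the 18 it was above the preset, up to 0.847 for ribosomal proteins. With fry 16 lists were called, among them p53 targets (adjusted p = 0.0186), which camera had not called. Of the 18, fry did not call metalloproteinases (adjusted p = 0.0537), mitotic genes (0.12) or ribosomal proteins (0.11). The ACTB ratio on these arrays was 0.697 against 0.893 untreated. In the cholesterol list 3 of 19 genes rose and 11 did when adjusted over the list alone (adjusted p = 1.67e-07, and adjusted p = 0.0847 with an estimated correlation). All 29 measured proteasome genes lay above 0, by a mean of 0.34 on the log2 scale (adjusted p = 2.3e-12, and adjusted p = 0.118 with an estimated correlation). None of them passed over all genes and 10 were higher when adjusted over the list alone, led by PSMC2 (3153 ± 69 untreated and 4919 ± 349 at 24 h, adjusted p = 0.0539) and PSMB6 (1622 ± 54 and 2446 ± 68, adjusted p = 0.061). For PSMC2, 1 of 3 probe sets had the opposite sign. NRF2 targets of the oxidative stress response shifted up (adjusted p = 2.76e-05, and adjusted p = 0.0743 with an estimated correlation), with none of 25 past the threshold over all genes and 12 higher when adjusted over the list alone. HMOX1, heme oxygenase 1, measured 538 ± 27 and 893 ± 58 (adjusted p = 0.0502).

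The ATF4 list shifted up at 24 h as well (adjusted p = 0.000472, and adjusted p = 0.0847 with an estimated correlation), where asparagine synthetase, ASNS, rose from 548 ± 21 to 1065 ± 41 (adjusted p = 0.022) and 43 of 44 genes did not pass, 9 being higher and 2 lower when adjusted over the list alone. The other probe set of ASNS had the opposite sign, and its call was lost with their mean (adjusted p = 0.11). Autophagy genes shifted up (adjusted p = 0.00362, and adjusted p = 0.0847 with an estimated correlation): WIPI1 rose from 213 ± 17 to 427 ± 15 (adjusted p = 0.0278) and 32 of 33 did not pass, with 5 higher and 2 lower when adjusted over the list alone. Lysosomal genes shifted up (adjusted p = 0.0365, and adjusted p = 0.209 with an estimated correlation), with none of 43 past the threshold and 7 higher and 2 lower when adjusted over the list alone. RRAGC measured 831 ± 24 and 1518 ± 216 (adjusted p = 0.0502). The lysosomal call was also lost with the mean over probe sets (adjusted p = 0.0966), the filter at the 40th percentile (0.053) and median centring (0.0523). It was lost in 3 runs without 1 array as well (camera adjusted p up to 0.112). The list of fatty acid synthesis shifted up (adjusted p = 0.032, and adjusted p = 0.138 with an estimated correlation), where LPIN1, a phosphatidate phosphatase, rose from 105 ± 10 to 228 ± 8 (adjusted p = 0.0333), 1 of 14 genes, and 3 when adjusted over the list alone. That call was lost with the mean over probe sets, with the filter at the 40th percentile and in 3 runs without 1 array.

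Metallothioneins (adjusted p = 0.0202, and adjusted p = 0.243 with an estimated correlation), histone genes (adjusted p = 0.000567, and adjusted p = 0.105 with an estimated correlation) and ribosomal protein genes (adjusted p = 1.63e-07, and adjusted p = 0.504 with an estimated correlation) shifted up with no member past the threshold over all genes. Of these families 1, 6 and 0 genes were higher when adjusted over the list alone, and 1 histone gene was lower. Their probe sets may share signal between paralogs, the metallothionein call was lost with the mean over probe sets, and the direction of ribosomal proteins relative to other genes turned under quantile normalization.

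TGF-beta targets shifted down at 24 h (adjusted p = 0.00036, and adjusted p = 0.114 with an estimated correlation). ID1 and ID3 fell, 24 of 26 genes did not pass and 4 were lower when adjusted over the list alone. SRF/MRTF cytoskeletal targets shifted down (adjusted p = 0.00207, and adjusted p = 0.14 with an estimated correlation), with none of 24 past the threshold and 8 lower when adjusted over the list alone. MYL9 measured 459 ± 21 and 252 ± 9 (adjusted p = 0.0502), with 1 of 2 probe sets of the opposite sign. Integrin and focal adhesion genes shifted down (adjusted p = 0.00362, and adjusted p = 0.114 with an estimated correlation), with none of 35 past the threshold and 6 lower when adjusted over the list alone. Their leading members were BCAR1 (157 ± 10 and 89.2 ± 8.6, adjusted p = 0.0518) and CAV1, caveolin 1 (3049 ± 66 and 2018 ± 156, adjusted p = 0.0528). For BCAR1, 1 of 2 probe sets had the opposite sign. Collagen and fibrillar matrix genes shifted down (adjusted p = 0.00362, and adjusted p = 0.163 with an estimated correlation). In that list LOX fell, 47 of 49 genes did not pass, and 5 were lower and 2 higher when adjusted over the list alone. COL3A1, named after its values were seen, rose from 2.13 ± 0.55 to 19.8 ± 9.0, near background (adjusted p = 0.0487), with 1 of 5 probe sets of the opposite sign. Its call was lost with the mean over probe sets (adjusted p = 0.376) and with the compared groups alone.

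Mesenchymal genes shifted down (adjusted p = 0.0202, and adjusted p = 0.115 with an estimated correlation), SNAI2 being the 1 of 20 that fell, and 1 was lower and 1 higher when adjusted over the list alone. Mitotic genes shifted down (adjusted p = 0.0201, and adjusted p = 0.351 with an estimated correlation), with none of 50 past the threshold over all genes or adjusted over the list alone. The lists of plasminogen and serine proteases (adjusted p = 0.00362, and adjusted p = 0.105 with an estimated correlation) and of matrix metalloproteinases and their inhibitors (adjusted p = 0.0251, and adjusted p = 0.209 with an estimated correlation) shifted down with none of 22 and 24 genes past the threshold. Adjusted over the list alone, 3 genes were lower in each and 1 metalloproteinase gene was higher.

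Among the protease genes fixed beforehand as inhibitor targets (MMP1, MMP2, MMP14, CTSB, CTSD, CTSL and PLAU), none passed the threshold in any comparison. They are a part of the protease classes that the mix inhibits. MMP2 measured 516 ± 27 untreated, 300 ± 93 at 4 h and 234 ± 44 at 24 h (adjusted p = 0.181 and 0.0551), and CTSB 2089 ± 28, 1383 ± 249 and 1302 ± 90 (adjusted p = 0.148 and 0.074). Of the 3 probe sets of MMP2, 2 had the opposite sign at 4 h and 1 at 24 h, as had 1 of 5 for CTSB at 4 h. MMP14 measured 404 ± 26, 310 ± 81 and 303 ± 7 (adjusted p = 0.411 and 0.325), and MMP1 308 ± 16, 329 ± 29 and 257 ± 12 (adjusted p = 0.815 and 0.334). CTSD, CTSL and PLAU stood at 79.3 ± 25.2, 735 ± 66 and 1763 ± 291 at 24 h against 104 ± 13, 841 ± 101 and 2009 ± 64 untreated (adjusted p = 0.454, 0.525 and 0.64). Lists of markers of epithelial, endothelial, haematopoietic and skeletal muscle cells did not shift at 4 h or 24 h, with lowest adjusted p of 0.562 and 0.484, and 0 of their 72 genes passed over all genes. Adjusted over the list alone, 2 of 14 endothelial genes were higher and 1 lower at 4 h, 2 were higher and 3 lower at 24 h, and 1 of 21 epithelial genes was higher and 1 lower at 24 h. No haematopoietic or muscle gene passed there.

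The harvest time of the untreated cells is not given, so time in culture may have added to the 24 h changes and to those between 4 h and 24 h. The 24 h counts moved strongly when 1 array was left out. They rose to 106 higher and 150 lower without replicate 2 of the 4 h group, which enters only through the shared spread. Without any 1 of the 24 h arrays, or without untreated replicate 2 or 3, they fell to 0 or 1 in all. In those runs 2374 to 2778 genes still had an unadjusted limma p under 0.05, with 989 expected by chance. The loss followed whichever 24 h array was removed, so it does not single out 1 array. A filter at the 40th percentile gave 288 and 289, and a pseudocount of 1 gave 0 and 1.

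**Figure D3:**
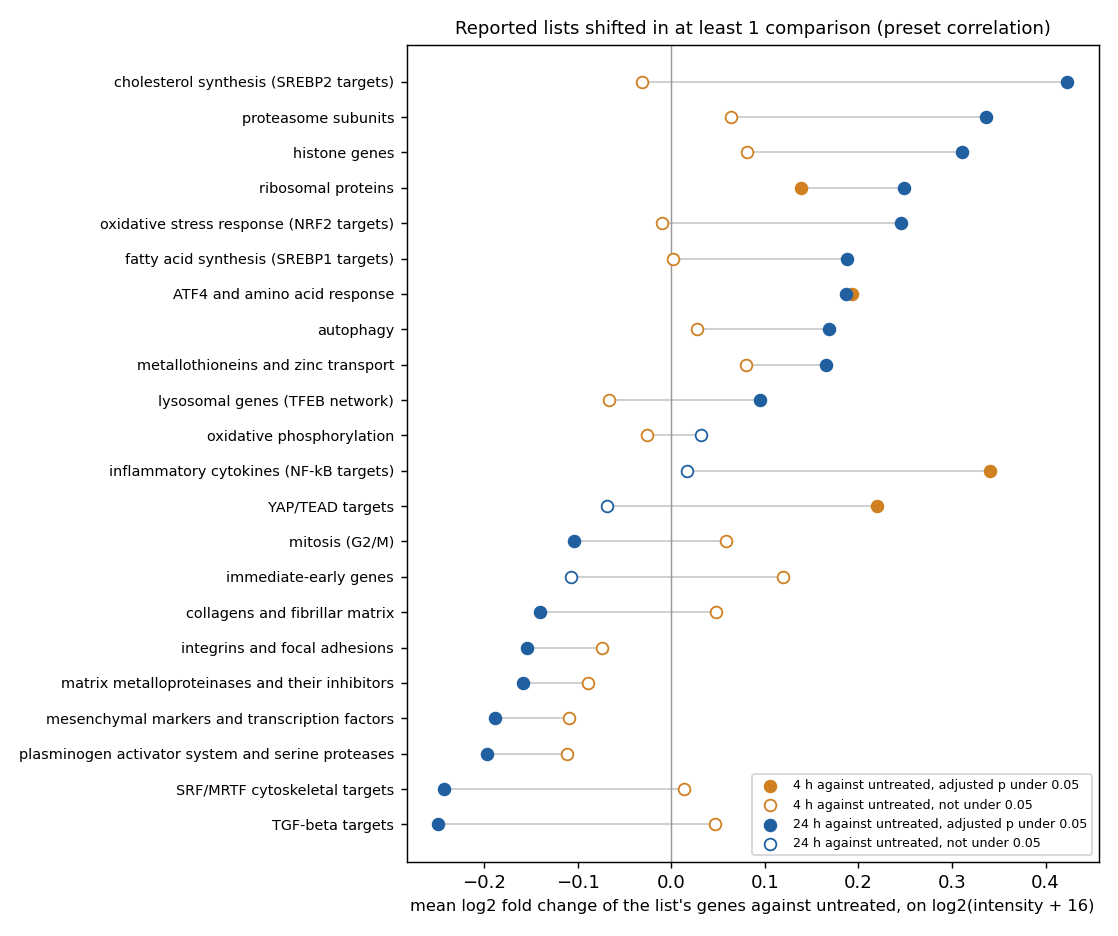
Mean log2 fold change against untreated, on log2(intensity + 16), of the genes in each reported list that shifted in at least 1 of the 3 comparisons; filled points have an adjusted p under 0.05 at the preset correlation. The cholesterol list moved from -0.03 at 4 h to 0.42 at 24 h and the NF-kB list from 0.34 to 0.02, and the directions, relative to other genes, of the ribosomal list and of oxidative phosphorylation for 24 h against 4 h turn under quantile normalization.

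Between 4 h and 24 h, 5 genes were higher and 23 lower. CXCL8 fell from 657 ± 42 to 106 ± 14, a level that did not pass against untreated (log2 change -0.22, adjusted p = 0.53; log2 change from 4 h -2.47 ± 0.15 SE, adjusted p = 0.000446), and CCN2 fell from 1140 ± 253 to 256 ± 32 (adjusted p = 0.00652). TNFAIP3 fell from 229 ± 7 to 88.0 ± 8.8 (adjusted p = 0.00652), EGR1 from 177 ± 11 to 81.3 ± 8.0 (adjusted p = 0.0298), and IL1B, the gene of interleukin 1 beta, from 1873 ± 233 to 937 ± 21 (adjusted p = 0.0262). Unlike the others, IL1B had not passed at 4 h against untreated (log2 change 0.11, adjusted p = 0.794). At 24 h it was called below untreated (log2 change -0.87, adjusted p = 0.0333). PTGS2, GPR84 and STC2 also had large falls, to 11.6 ± 6.3, 14.2 ± 5.4 and 137 ± 12 from 54.5 ± 2.9, 60.9 ± 8.7 and 358 ± 43. MSMO1 (1131 ± 71 to 2551 ± 167, adjusted p = 0.00652), HMOX1 (406 ± 50 to 893 ± 58, adjusted p = 0.0151) and SQLE (395 ± 47 to 730 ± 19, adjusted p = 0.0374) rose, as did OSER1-DT (4.87 ± 0.80 to 25.3 ± 5.8, near background) and ARHGAP5-AS1 (28.1 ± 5.4 to 68.9 ± 3.2). With the mean over probe sets the calls of EGR1, STC2, SQLE and OSER1-DT were lost (adjusted p = 0.13, 0.0692, 0.0843 and 0.385), EGR1 and OSER1-DT each having 1 of 3 probe sets of the opposite sign. Under median centring the calls of EGR1 and IL1B were lost.

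At the preset correlation 9 lists were higher and 7 lower at 24 h than at 4 h, and 6 of these held with an estimated correlation. Those were cholesterol synthesis (adjusted p = 3.08e-11, and adjusted p = 0.0416 with an estimated correlation), NRF2 targets (2.23e-07 and 0.0283), lysosomal genes (6.64e-06 and 0.0416) and autophagy genes (0.000723 and 0.0416), which were higher, and NF-kB targets (1.08e-05 and 0.0416) and TGF-beta targets (3.87e-07 and 0.0416), which were lower. In the cholesterol list 2 of 19 genes rose and 11 did when adjusted over the list alone. HMOX1 was the 1 of 25 NRF2 targets that rose, with 11 higher and 1 lower when adjusted over the list alone. Of 30 NF-kB targets CXCL8, TNFAIP3, IL1B and PTGS2 fell, with 8 lower and 1 higher when adjusted over the list alone. None of 43 lysosomal, 33 autophagy and 26 TGF-beta genes passed over all genes, and 0, 4 and 8 moved in the direction of their list when adjusted over the list alone. INHBA, a TGF-beta family ligand gene, measured 149 ± 16 at 4 h and 83.6 ± 5.1 at 24 h (adjusted p = 0.0545).

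The other 10 calls were lost with an estimated correlation. Proteasome genes were higher by a mean of 0.27 on the log2 scale, with all 29 above 0, none past the threshold and 3 when adjusted over the list alone (adjusted p = 7.66e-12, and adjusted p = 0.107 with an estimated correlation). Fatty acid synthesis (adjusted p = 0.0644 with an estimated correlation), histone (0.0661), ribosomal protein (0.586) and oxidative phosphorylation genes (0.43) were higher with no gene past the threshold and 3, 4, 0 and 0 when adjusted over the list alone. The direction of the last pair turned under quantile normalization, and the call for oxidative phosphorylation was also lost with the mean over probe sets, with the filter at the 60th percentile and with the compared groups alone. When each array was left out in turn, that call was lost in 7 of 9 runs. The ribosomal call was lost in 1 run, without replicate 2 of the 4 h group (camera adjusted p = 0.317). YAP/TEAD targets were lower (adjusted p = 1.49e-05, and adjusted p = 0.0667 with an estimated correlation), with CCN2 the 1 of 26 that fell, and 6 lower and 1 higher when adjusted over the list alone. Immediate-early genes were lower (adjusted p = 3.51e-05, and adjusted p = 0.211 with an estimated correlation), with EGR1 the 1 of 34 that fell, and 9 lower and 2 higher when adjusted over the list alone. SRF/MRTF targets, collagens and mitotic genes were lower with no gene past the threshold (adjusted p = 0.0742, 0.0748 and 0.172 with an estimated correlation). Adjusted over the list alone, 5, 7 and 0 of them were lower and 1 collagen-list gene was higher. Without any 1 array the counts for this comparison fell to between 1 and 3 higher and between 5 and 15 lower, and median centring gave 6 and 14.

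The changes at 4 h and 24 h were compared with each other. Of the 46 genes higher at 4 h, 38 lay above 0 at 24 h, and 9 were called lower at 24 h than at 4 h. Both lists of higher genes held MAFF, NFKBIA and, named after their values were seen, IL7R, RPS6KA5, SERTAD2 and ZNF264, which is 6 genes against 0.1 for independent lists. With the mean over probe sets the 24 h calls of all but NFKBIA were lost, as were the 4 h calls of RPS6KA5 and ZNF264 (limma adjusted p = 0.164 and 0.45). No gene was called lower at both times. Across the 19775 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.567 and Spearman rho = 0.543, against a simulated r of 0.499 ± 0.008 for unchanged groups that share the untreated arrays. The covariance was 0.0442 against a simulated 0.0238, a difference of 0.0204. The simulation drew each gene independently, so its SD leaves out variation that genes share on an array. Without 1 array the observed r ran from 0.4845 to 0.6267. The simulated value is for 3 arrays in every group, so it does not apply to those runs and the range decides nothing here. With a pseudocount of 1 the observed r was 0.5025, near the simulated value made with the pseudocount of 16. Given that value and the shared variation left out, an excess of r over unchanged groups was not established. The 3 untreated arrays were not split between the comparisons, since 1 part would have held a single array, so part of any excess in shared calls may come from them.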

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

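The tests of control transcripts, of the place of single arrays and of RNA quality were chosen after the results were seen; the count of other splits was planned. Earlier forms of the array and RNA quality tests were replaced after their results were seen; with a fixed bound, the earlier test of a wrong label had left it undecided. Of the 10 ways to split the 6 arrays of each comparison, 1 split, the real one, gave as many genes at 4 h (49 genes, highest other split 0), at 24 h (92, highest other 0) and for 24 h against 4 h (28, highest other 0). With 10 splits no share under 0.05 can be reached.

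These genes had a change at 24 h that differed from the change at 4 h, given here as the log2 change at 24 h minus that at 4 h. That difference is the comparison of 24 h with 4 h reported above, for genes and lists alike, so it is no further test. It was -2.47 for CXCL8, -2.07 for CCN2, -1.38 for PTGS2, -1.36 for GPR84, -1.29 for STC2, -1.24 for TNFAIP3, -1.21 for ALDH1A3, -1.14 for LYPD1, -0.99 for EGR1, -0.98 for IL1B, and, named after their values were seen, -0.93 for BCL2A1 and -0.93 for CD274. It was 1.16 for MSMO1, 1.11 for HMOX1, 0.98 for OSER1-DT, 0.95 for ARHGAP5-AS1 and 0.86 for SQLE (0.865 before rounding). With the mean over probe sets the calls of EGR1, STC2, SQLE, OSER1-DT and CD274 were lost.

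Among gene lists, the mean log2 change was larger at 24 h than at 4 h by 0.455 for cholesterol synthesis, 0.272 for the proteasome, 0.255 for NRF2 targets, 0.23 for histones, 0.187 for fatty acid synthesis, 0.161 for lysosomal genes, 0.142 for autophagy, 0.11 for ribosomal proteins and 0.0568 for oxidative phosphorylation; the last pair turned under quantile normalization. With each array left out in turn, the difference ran from 0.03 to 0.213 for ribosomal proteins, whose call was lost in 1 run. For oxidative phosphorylation it ran from 0.0205 to 0.106, and the call was lost in 7 runs. The difference was -0.325 for NF-kB targets, -0.296 for TGF-beta targets, -0.289 for YAP/TEAD targets, -0.257 for SRF/MRTF targets, -0.226 for immediate-early genes, -0.187 for collagens and -0.163 for mitotic genes. Of these 16, only cholesterol synthesis, NRF2, lysosomal, autophagy, NF-kB and TGF-beta lists held with an estimated correlation; the other 10 were lost there (adjusted p from 0.0644 for fatty acid synthesis to 0.586 for ribosomal proteins).

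The spike transcripts, which no gene comparison uses, were brighter after treatment by 0.884 at 4 h and 1.31 at 24 h on the log2 scale. Array brightness or hybridization would have raised the hybridization controls alike, and these rose by 0.15 at 24 h, which argues against it. The 4 transcripts rose by 1.01 to 1.48 at 24 h. More spike mix or less total RNA per reaction in the treated groups, or a lower share of messenger RNA in total RNA after treatment, could each give this; the labels state 6 µg of total RNA for all samples, which speaks against a planned difference in input, but the amounts used per reaction, the spike amounts and the yield per cell were not analysed here, so these cannot be told apart.

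Replicate 2 of the 4 h group lay near the untreated arrays. Each 4 h and untreated array was left out in turn, genes with p under 0.001 at 4 h were found without it, and its share of their change was taken. Replicate 2 showed a median share of 0.503 (bootstrap interval 0.401 to 0.588, 254 genes), above the 0.0713 to 0.258 of the untreated arrays, which argues against an untreated array with a wrong label. It was below the 0.852 and 0.911 of the other 4 h arrays, which a weaker or shorter treatment of this culture could give, but over the genes called without it (9) its share was 0.926 against 1.08 and 0.925; that explanation stays open, as does RNA quality, since its ACTB ratio was the highest of its group. Its share was 0.743 over 139 rising genes and 0.212 over 115 falling ones; over falling genes the untreated arrays gave 0.318 to 0.524, so only the rising genes separate it from them.

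The ACTB ratio was low on all 24 h arrays and on replicates 1 and 3 at 4 h, which showed 1.24 times the drop at 24 h and would show the 24 h changes in full if RNA quality were the whole cause. Their share of the 24 h change was -0.044 for the cholesterol list, 0.376 for proteasome genes, 0.584 for the 43 genes called higher and 0.457 for the 49 called lower, which argues against it as the whole cause. The called genes were chosen for a large change at 24 h, which lowers their shares somewhat, and a partial effect stays open. Over the 18 shifted lists the share ran from -0.941 for mitotic genes and -0.754 for lysosomal genes, through 0.06 for TGF-beta targets, to 0.862 for metalloproteinases, 0.88 for ribosomal proteins (whose direction relative to other genes turned under quantile normalization) and 0.966 for ATF4 targets, and RNA quality could account for lists with a share near 1. An effect of inhibition at 24 h remains a hypothesis, since array measures and treatment move together, and extra time in culture, untested because the harvest time of the untreated cells is not given, stays open for the 24 h changes and for those between 4 h and 24 h.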

How the results depend on the processing

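The pseudocounts of 1 and 64 were chosen after seeing the data; the other settings were planned. Single-gene counts depended strongly on the settings, while most list calls kept their side at the preset correlation. Counts are given as higher and lower genes for 4 h, then 24 h, then 24 h against 4 h, where they moved by over 1.5 times from 46 and 3, 43 and 49, and 5 and 23. The mean of all probe sets gave 25 and 1, then 18 and 31, with 3 lists at 4 h in place of 5. Each probe set on its own gave 7 and 0, 9 and 20, and 3 and 11. The filter at the 40th percentile gave 142 and 35, 288 and 289, and 41 and 84, and at the 60th 296 and 162, 597 and 586, and 138 and 190. Of the 49, 92 and 28 genes called without a filter, 45, 86 and 27 were called with the first. Quantile normalization gave 5 lower at 4 h and 9 higher for 24 h against 4 h, and median centring 16 higher at 4 h and 14 lower for 24 h against 4 h. Trend and robust eBayes gave 244 and 108, 502 and 457, and 109 and 145. The compared groups alone gave 2 and 0, 86 and 114, and 0 and 1. A minimum log2 change of 1 left 20 and 0, 9 and 15, and 2 and 11. Pseudocount 1 gave 6 and 0, 0 and 1, and 2 and 7, and pseudocount 64 gave 184 and 89, 420 and 406, and 105 and 146. Filters test fewer genes and remove dim, noisy ones; otherwise the cause was not tested. Apart from the block described below, settings over all genes with a count of 0, left-out arrays included, had 1800 to 2778 genes at an unadjusted limma p under 0.05, with 989 expected by chance; each probe set on its own had 6027 at 4 h, with 2731 expected, and the minimum change left 7 falls at 4 h.

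With the correlation estimated, 0, 0 and 6 lists were called in place of 5, 18 and 16. The correlation of 4 h and 24 h changes, 0.567, moved to 0.622 and 0.659 with the filters, 0.503 with pseudocount 1 and 0.626 with pseudocount 64. The value with pseudocount 1 lay near the 0.499 simulated for unchanged groups, which was made with the pseudocount of 16.

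With the replicate number as a replicate block, the counts were 3 and 0, 0 and 1, and 0 and 3, beside 2364, 3041 and 2145 genes at an unadjusted limma p under 0.05 (989 by chance). The list calls of lysosomal genes and fatty acid synthesis at 24 h and of oxidative phosphorylation for 24 h against 4 h were not made there. Same-numbered arrays had correlations of -0.0441 to 0.0573 over 9 pairs, others -0.0465 to 0.0794, so the numbers were not taken to pair the arrays, for which every pair would need a correlation over 0.1. Not every array was best with its own number, but 13 of 18 comparisons were, against 6 by chance, and all 6 between 4 h and 24 h, a hint of shared handling that the labels do not state.

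Without 1 array, counts ranged from 3 to 14 higher and 0 to 1 lower at 4 h, 0 to 106 and 0 to 150 at 24 h, and 1 to 3 and 5 to 15 for 24 h against 4 h. Lists numbered 4 to 7, 15 to 19 and 15 to 18, and the correlation ranged from 0.485 to 0.627. At 24 h the calls of lysosomal genes and fatty acid synthesis were lost in 3 runs each. Those of metalloproteinases and mitotic genes were lost in 2 each, and that of metallothioneins in 1. The ribosomal call at 4 h was lost in 2. The highest 24 h counts were without PI 4 h replicate 2.

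Directions turned in these cases. RUNX2 at 4 h (0.0364), SARS1 at 24 h (-0.11) and MMP14 for 24 h against 4 h (-0.0415) turned with the mean of all probe sets, and MMP14 with pseudocount 64 (-0.0020). Under quantile normalization the camera direction, relative to other genes, turned for ribosomal proteins at 24 h (mean log2 change 0.0153) and for 24 h against 4 h (-0.0142), and for oxidative phosphorylation (-0.0176). Without PI 4 h replicate 3 that direction turned for ribosomal proteins at 4 h, with the mean still above 0 (0.0355; range to 0.2188). For 24 h against 4 h, leaving out 1 array turned MMP14 (-0.2183 and -0.0170, range to 0.1458), PLAU (-0.0967 and -0.0400, range to 0.1984), CTSB (0.0194, range from -0.2286) and CTSD (0.0441 and 0.1846, range from -0.202), none of which passed the threshold in any such setting; the cause was not tested. Of 72 list results that did not pass, 69 of 1428 reruns turned, 0 of them past the threshold, and 12 passed in at least 1 rerun; these are given as counts, a choice made after many were seen to turn. No detection calls were used, so signal over background limits the dim genes.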

Other observations

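The zinc finger test was written before its result was seen, though the pattern was noticed in the called genes. The genes of this paragraph and the next were named after their values were seen. At 4 h further genes of NF-kB signalling rose: MAP3K14, a kinase of the non-canonical pathway, from 85.7 ± 0.5 to 204 ± 19 (limma adjusted p = 0.00938), and NFKBIE, an inhibitor of NF-kB, from 109 ± 5 to 208 ± 24 (adjusted p = 0.0369). BCL2A1, an anti-apoptotic gene, rose from 76.8 ± 10.1 to 142 ± 6 (adjusted p = 0.0444) and CD274, which encodes PD-L1, from 115 ± 9 to 210 ± 20 (adjusted p = 0.0442). At 24 h both stood at 66.9 ± 4.7 and 102 ± 5, below their 4 h levels (adjusted p = 0.0262 each). Under median centring the 4 h calls of NFKBIE, BCL2A1 and CD274 were lost, as was that of BCL2A1 for 24 h against 4 h. The 4 h call of BCL2A1 was also lost under quantile normalization. BRD2, a bromodomain gene, rose from 657 ± 83 to 1432 ± 96 at 4 h (adjusted p = 0.0181).

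At 24 h the receptor gene TGFBR2 fell from 1062 ± 71 to 533 ± 45 (adjusted p = 0.0229) and HAS2, a hyaluronan synthase, from 34.5 ± 3.6 to 12.4 ± 4.1 (adjusted p = 0.0474), near background. CST3, which encodes cystatin C, an inhibitor of cysteine proteases, fell from 864 ± 50 to 406 ± 34 (adjusted p = 0.0485). FUT8 and GMDS, enzymes of protein fucosylation and GDP-fucose synthesis, fell from 465 ± 39 to 240 ± 35 (adjusted p = 0.0451) and from 236 ± 20 to 120 ± 4 (adjusted p = 0.0435). The osmolyte transporter genes SLC5A3 and SLC6A6 rose from 371 ± 30 to 716 ± 75 (adjusted p = 0.0497) and from 571 ± 69 to 1047 ± 88 (adjusted p = 0.0333). With the mean over probe sets the calls of CST3, GMDS, SLC5A3 and SLC6A6 at 24 h were lost (adjusted p = 0.366, 0.229, 0.191 and 0.31), as were those of CD274 (0.243 at 4 h and 0.195 for 24 h against 4 h). The same cautions on single arrays apply as for the other 24 h calls.

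Of the genes called higher at 4 h, 4 are named as zinc finger genes: ZNF264, ZNF275, ZNF281 and ZNF431, of which only ZNF275 kept its call with the mean over probe sets. A hypothesis is that zinc finger genes may shift together at 4 h. Over all 466 genes named ZNF and a number, 288 lay above 0 at 4 h, with a median log2 change of 0.09, and camera with an estimated correlation gave p = 0.0125 in the upward direction. The mean change was 0.105, 0.106 and 0.103 on the 4 h arrays, replicate 2 included, and between -0.0405 and 0.0404 on the untreated arrays. At 24 h 269 genes lay above 0 and the set did not pass, and neither did the difference between 24 h and 4 h, so a difference between the times was not shown. The set was chosen from these data, and the test is not independent of the pattern that led to it.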
